A study of Mus musculus with 6 samples.

How the data were processed

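RNA of 6 mouse hearts, 3 control (Srsf3Fl/Fl) and 3 cKO (Srsf3Fl/Fl-βMHC-Cre), was extracted with Trizol, and polyadenylated RNA was sequenced from libraries made with a stranded total RNA kit, per the labels' protocols. Groups were taken from the sample descriptions. Replicate numbers shared by the groups follow the order of accession only and pair nothing. The submitters' processing notes name FastQC 0.10.1, Trimmomatic 0.38, kallisto 0.46.0 and DESeq2 1.24.0, and the builds GRCm38, mm9 and mm10. The versions of vast-tools, sleuth and featureCounts, the thresholds of the other pipelines and the release of the transcriptome are not given in the sources used here.

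The authors deposited a table of genes with their own comparison. Per the file headers it holds the mean normalized signal over all libraries, the log2 fold change with its standard error, the Wald score and the p-value with its adjusted value, from kallisto estimates tested by the authors with DESeq2. Of 36558 genes, 25665 have a p-value and 15929 an adjusted p, and 9736 have a p-value without an adjusted one. The deposited score equals the log2 fold change divided by its standard error, and the adjusted p equals the Benjamini-Hochberg value over the 15929 genes. The authors also deposited the IDs of genes that passed in each of 3 pipelines. The deposited table of splicing events gives, per the file headers, the inclusion level of 265079 events as a fraction in each group, their difference, and a score for the minimum change that is exceeded with probability 0.95, as vast-tools writes it with the replicates of a group combined. Fractions are printed here as percentages. The deposited sheet of 610 events equals the events with a minimum change of at least 10 points.

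No values per library were used, since these tables hold the authors' comparison of groups. The tests chosen before the data were examined for per-library values, a count test across genes and a linear model of inclusion reads, were therefore replaced by the fallback fixed with them: the authors' log2 fold change and adjusted p for genes, and the authors' minimum change for events. No column used here was assigned to a single sample. Depth per sample is unknown, so no counting intervals are given for single genes. No paired fit, no fit without a library and no regrouping of libraries could be made.

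Gene IDs were matched to GENCODE M21 (GRCm38) for symbols and positions: 35856 IDs matched and 702 did not, of which 12 passed the test and 8 of these 12 had a row equal to that of a matched gene. Counts of genes over the whole table include them, and 15712 matched genes were used for lists. Event coordinates are those of the deposited table, on mm9, and the symbols of events were matched to gene symbols directly for 10562 of 11908 genes, through older symbols for 1050, and not for 296. Introns of Myh7 were numbered by matching their lengths and order to the introns of its GENCODE M21 transcript.

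The group that a fold change is relative to was settled from the events. For exons within 3 points of full inclusion in both groups (introns within 3 points of 0), the log2 ratio of that distance in control over cKO was taken per gene as the median of at least 3 events, and centred on the median over genes. Introns gave the same direction, with 433 of 577 genes (75.0%) of equal sign.

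The 38 gene lists for expression, and 1 more for splicing alone, were fixed before the data were examined. For each list the members at adjusted p under 0.05 over all genes and those passing when adjusted over the list alone were counted. The list was tested against all other genes with camera (cameraPR of limma, two-sided) on the authors' Wald score, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 5 tested members. It gave 21 of 38 lists at an adjusted p under 0.05, 6 higher and 15 lower. Camera with an estimated correlation could not be run, since it needs values per library. With a preset correlation of 0.05 instead, 15 of the 21 list calls hold, and the SR protein, hnRNP, fatty acid, sarcomere, calcium handling and erythroid lists lose theirs. A rank-based form of cameraPR, chosen after the result was seen, gave 24 lists: the calcium handling list lost its call, and the mitochondrially encoded, unfolded protein response, adipocyte and atrial lists gained one. Directions of events were tested with exact two-sided binomial tests, shares with Fisher's exact test and odds ratios with exact 95% intervals. Other tests used permutations of 100000 draws or 10000 matched random lists.

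Genes named in the text follow a rule fixed before the data were examined: Srsf3 and Oma1, the 10 largest rises and 10 largest falls among genes that passed with a mean of at least 10 normalized counts (predicted genes and pseudogenes left out), and up to 4 members per list by smallest adjusted p, or 2 by abundance for a list without any. The part of the rule asking that all libraries of a group lie above those of the other could not be applied. Events named are those of Srsf3, the 10 largest rises and 10 largest falls, and up to 4 per list for heart exons, SR proteins and mitochondrial lists, ranked by the minimum change in place of an adjusted p. Events of Oma1, Opa1 and Myh7, and genes said to be taken after their values were seen, were added afterwards. Some genes and events that this rule selects are not reported here. The alternatives tried were other thresholds, abundance filters, the authors' other pipelines, other settings of the set test and 1 event per gene.

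The steps were tested on simulated data. In 20 draws of scores for 15700 genes with 8 lists moved in each, camera recovered 67 of 80 lists moved by 1 standard error and 80 of 80 moved by 2, and called 7 of 600 unmoved lists (1.17%). The scores were drawn independently for each gene, so these rates do not cover lists whose members vary together. With 200 genes changed 2-fold among simulated exon reads, the depth step gave the right sign for all 110 that had enough exons, out of 5833 genes. The simulated inclusion levels followed the relation to depth that the step assumes, so that relation was not tested. Changes smaller than 2-fold were not simulated, and the genes that passed had a median absolute log2 fold change of 0.43. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.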

Results

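Hearts of control mice, in which both copies of Srsf3 are flanked by loxP sites (Srsf3Fl/Fl), were compared with hearts of mice that also carry βMHC-Cre (cKO). This transgene expresses Cre recombinase under the Myh7 promoter in cardiomyocytes from in utero development onward and removes the floxed part of Srsf3 there. SRSF3 is a splicing factor of the SR family, and the comparison asks what its loss in cardiomyocytes does to gene expression and splicing, with a view to mitochondria. Polyadenylated RNA of 3 control and 3 cKO hearts was sequenced from stranded libraries. The values used are the authors' fold changes for 36558 genes and their inclusion levels for 265079 splicing events, with 1 value per group for each event. The inclusion level, or PSI, is the percentage of a gene's transcripts that hold an exon or keep an intron. Read totals per sample were not used here, so the depth of each sample is unknown.

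The deposited gene values do not name the group that the fold change is relative to, and the direction was settled from the splicing values. Exons of near-full inclusion lie closer to 100% where more reads stand behind them, so their distance from it ranks the depth of each gene in cKO against control. Of 671 genes that passed the test and had such exons, 635 (94.6%) had a fold change of the same sign as this depth, relative to the median of all genes (exact binomial p = 1.29e-142). Positive values are therefore higher in cKO throughout. Across 7506 genes, which are not independent replicates, Spearman's correlation between fold change and depth was 0.64. The median depth behind these exons was higher in cKO by 0.39 on the log2 scale.

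**Figure D1:**
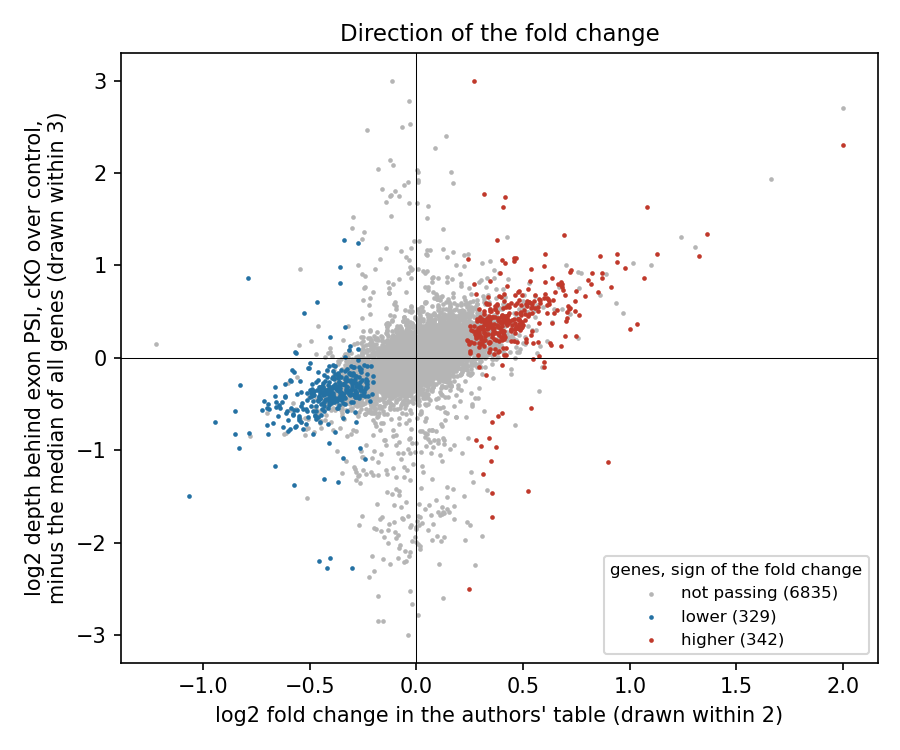
Log2 fold change of 7506 genes in the authors' deposited table (horizontal) against the log2 depth behind the same genes' exon inclusion values, cKO over control, minus the median of all genes (vertical). Each point is a gene, colored by the sign of the fold change where the adjusted p was under 0.05, and 635 of the 671 colored genes have the same sign on both axes.

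Srsf3 itself showed no difference in total RNA between cKO and control hearts. Its log2 fold change was 0.02 with a standard error of 0.07 and an adjusted p of 0.935 in the authors' deposited table, at a mean of 12870 normalized counts. The gene, on chromosome 17, is nevertheless among the 517 genes of a second list of the authors, made with sleuth. The alternative 3′ splice site of Srsf3 in the authors' deposited table of events was used at 0.958% in control and 0.789% in cKO. A sum over all transcripts of a gene in whole hearts does not separate an mRNA lacking the floxed part from an intact one, and other cell types keep the gene, so this value does not check the deletion.

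Against control hearts, cKO hearts had lower mRNA of the respiratory chain and ATP synthase, of the cell cycle and of ion channels and conduction, and higher mRNA of macrophage markers, p53 targets and autophagy genes. At an adjusted p under 0.05, 1130 of 15929 tested genes differed, 602 higher and 528 lower in cKO. Adjusted over all 25665 genes with a p-value, 921 passed, and of the genes named below Nmrk2, Cox6a2, Mrps35, Rbfox1, Rbpms, Vwf and Tagln did not. Most differences were small: the median absolute log2 fold change of these genes was 0.43, and 120 changed at least 2-fold, of which 110 rose and 10 fell. The authors' lists from other pipelines held 517 genes (kallisto with sleuth) and 171 genes (featureCounts), of which 384 and 80 were among the 1130. The 48 genes in all 3 lists comprised 46 higher and 2 lower in cKO.

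The largest rises included some genes of motile cilia and sperm. Axoneme and cilium genes as a family, picked by symbol after the values were seen, did not move together. Of 65, 4 rose and 4 fell, with a median of 0.03 (camera adjusted p = 0.324). The sizes were unlike in the authors' deposited table. The 4 that rose stood at 3.77 to 6.75, and Spag7, Spag5, Cfap20 and Ift122, which fell, at -0.28 to -0.41. Picking by symbol does not show that each member is an axoneme gene. Dnah10, an axonemal dynein heavy chain, rose by 6.75 on the log2 scale (SE 0.64, adjusted p = 2.76e-22) in the authors' deposited table. By the same comparison in the authors' deposited table, Drc1 of the dynein regulatory complex rose by 4.31 (SE 1.01), Tcte3, a dynein light chain, by 4.31 (SE 0.33) and Dpy19l2, needed for sperm head formation, by 6.70. Ubap1l rose by 5.14, Lrrc66 by 4.81, the GABA receptor subunit Gabrr2 by 3.81, the stomatin family member Stoml3 by 3.77 and the collagen Col20a1 by 3.76 in the authors' deposited table. Spp1, which encodes the secreted matrix protein osteopontin, rose by 3.82 (SE 0.36, adjusted p = 3.16e-22) in the authors' deposited table. These genes were scarce: mean normalized counts in the authors' deposited table were 214 for Dpy19l2, 19.2 for Drc1 and 78.8 for Spp1.

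Among the genes named by the fixed rule, the largest falls were smaller than the largest rises. With predicted genes and pseudogenes left out, Arhgap36 had the largest log2 fall at -2.05 (SE 0.31) in the authors' deposited table. The calcium channel subunit Cacng6 stood at -1.26, the latrophilin Adgrl3 at -1.18 and Nmrk2, a nicotinamide riboside kinase of muscle, at -1.07 (SE 0.36, adjusted p = 0.0445) in the authors' deposited table. The odorant receptor Olfr1039 had a log2 fold change of -1.03, the potassium channel Kcnn1 -0.99, the aldolase Aldoc -0.94, the glutathione transferase Gstp2 -0.92 and the transcription factor Irx2 -0.92 in the authors' deposited table.

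Nuclear genes of oxidative phosphorylation were lower in cKO as a block. All 80 tested members of the 4 lists for complexes I to IV and ATP synthase had negative fold changes, with a median of -0.28. Of them 25 fell, and 62 passed when adjusted over the 80 genes pooled. Of 36 complex I subunits, 11 fell (25 adjusted over the list alone), among them Ndufc2 at -0.37 (SE 0.09) and the core subunit Ndufs1 at -0.24 (SE 0.07) in the authors' deposited table. Complexes II and III had 5 of 13 genes lower (11 adjusted over the list alone), with Sdhb, the iron-sulfur subunit of succinate dehydrogenase, at -0.36 and Cyc1, cytochrome c1, at -0.30 in the authors' deposited table. Complex IV had 3 of 15 genes lower (14 adjusted over the list alone), with Cox5b at -0.32 and Cox6a2, the muscle form of its subunit, at -0.28 in the authors' deposited table. ATP synthase had 6 of 16 genes lower (13 adjusted over the list alone), with the catalytic subunit Atp5b at -0.36 (SE 0.10, adjusted p = 0.00677) and Atp5g3 at -0.31 in the authors' deposited table. By camera the lists were lower than other genes at adjusted p = 2.75e-13 (complex I), 1.71e-07 (complexes II and III), 7.48e-08 (complex IV) and 2.17e-09 (ATP synthase). Myeloid markers moved the other way in the same comparison, with a median of 0.57. Of the 80 genes, 13 were in the sleuth list and 0 in the featureCounts list, whose 80 genes shared with the 1130 all had an absolute log2 fold change of at least 0.88.

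Of the mitochondrially encoded mRNAs 0 of 13 passed, also when adjusted over the list alone, and 3 had an unadjusted p under 0.05 in the authors' Wald test, with 0 in the sleuth list. The abundant mt-Co1 had a log2 fold change of -0.05 and mt-Nd4 -0.01 in the authors' deposited table, and the list's median was -0.07, with 10 of 13 values negative (camera adjusted p = 0.0658, and 0.0291 by the rank-based test). The mitochondrial ribosome list had a median of -0.11 over 78 genes, of which 4 fell and 1 rose (3 and 1 adjusted over the list alone; camera adjusted p = 0.000282). Mrps35 stood at -0.34 and Mrps18b at 0.37 in the authors' deposited table. Of 30 genes of mitochondrial dynamics and quality control, 3 rose and 2 fell, the same counts adjusted over the list alone (camera adjusted p = 0.425). The proteases Lonp1 and Parl rose by 0.30 and 0.34, and the kinase Pink1 and the fusion protein Mfn1 stood at -0.36 and -0.33 in the authors' deposited table. Oma1, the stress-activated protease of the inner membrane, was not among them, at 0.04 with a standard error of 0.11 in the authors' deposited table. Among 18 regulators of mitochondrial biogenesis, the coactivator Ppargc1b was at -0.37 and the muscle regulator Perm1 at -0.25 in the authors' deposited table. These 2 were the members that passed, also adjusted over the list alone (camera adjusted p = 0.16).

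Fuel metabolism was lower as well, in the same hearts in which myeloid markers were higher. In the TCA cycle and pyruvate oxidation list 7 of 21 genes fell (8 adjusted over the list alone; camera adjusted p = 5.96e-08). Fumarate hydratase, Fh1, was at -0.51 (SE 0.12) and Dlat, the acetyltransferase of pyruvate dehydrogenase, at -0.43 (SE 0.07, adjusted p = 1.49e-07) in the authors' deposited table. Of 20 genes of glycolysis and glucose uptake, 4 fell (5 adjusted over the list alone; camera adjusted p = 0.000159), with the muscle phosphofructokinase Pfkm at -0.33 and the enolase Eno1 at -0.38 in the authors' deposited table. Of 30 genes of fatty acid uptake and oxidation, 4 fell (5 adjusted over the list alone), among them the acetyl-CoA synthetase Acss1 at -0.43, the long-chain dehydrogenase Acadl at -0.26 and the fatty acid carrier Fabp3 at -0.30 in the authors' deposited table. Their camera adjusted p was 0.00397, and 0.0515 with a preset correlation of 0.05. Iron and heme handling had 3 of 27 genes lower and 1 higher (4 and 1 adjusted over the list alone; camera adjusted p = 0.684). The heme oxygenase Hmox1 rose by 0.72 and Abcb8, a transporter of the inner mitochondrial membrane, stood at -0.49 in the authors' deposited table. In the antioxidant list 1 of 21 genes passed, also adjusted over the list alone: the mitochondrial superoxide dismutase Sod2 fell by 0.34 in the authors' deposited table (camera adjusted p = 0.0772).

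**Figure D2:**
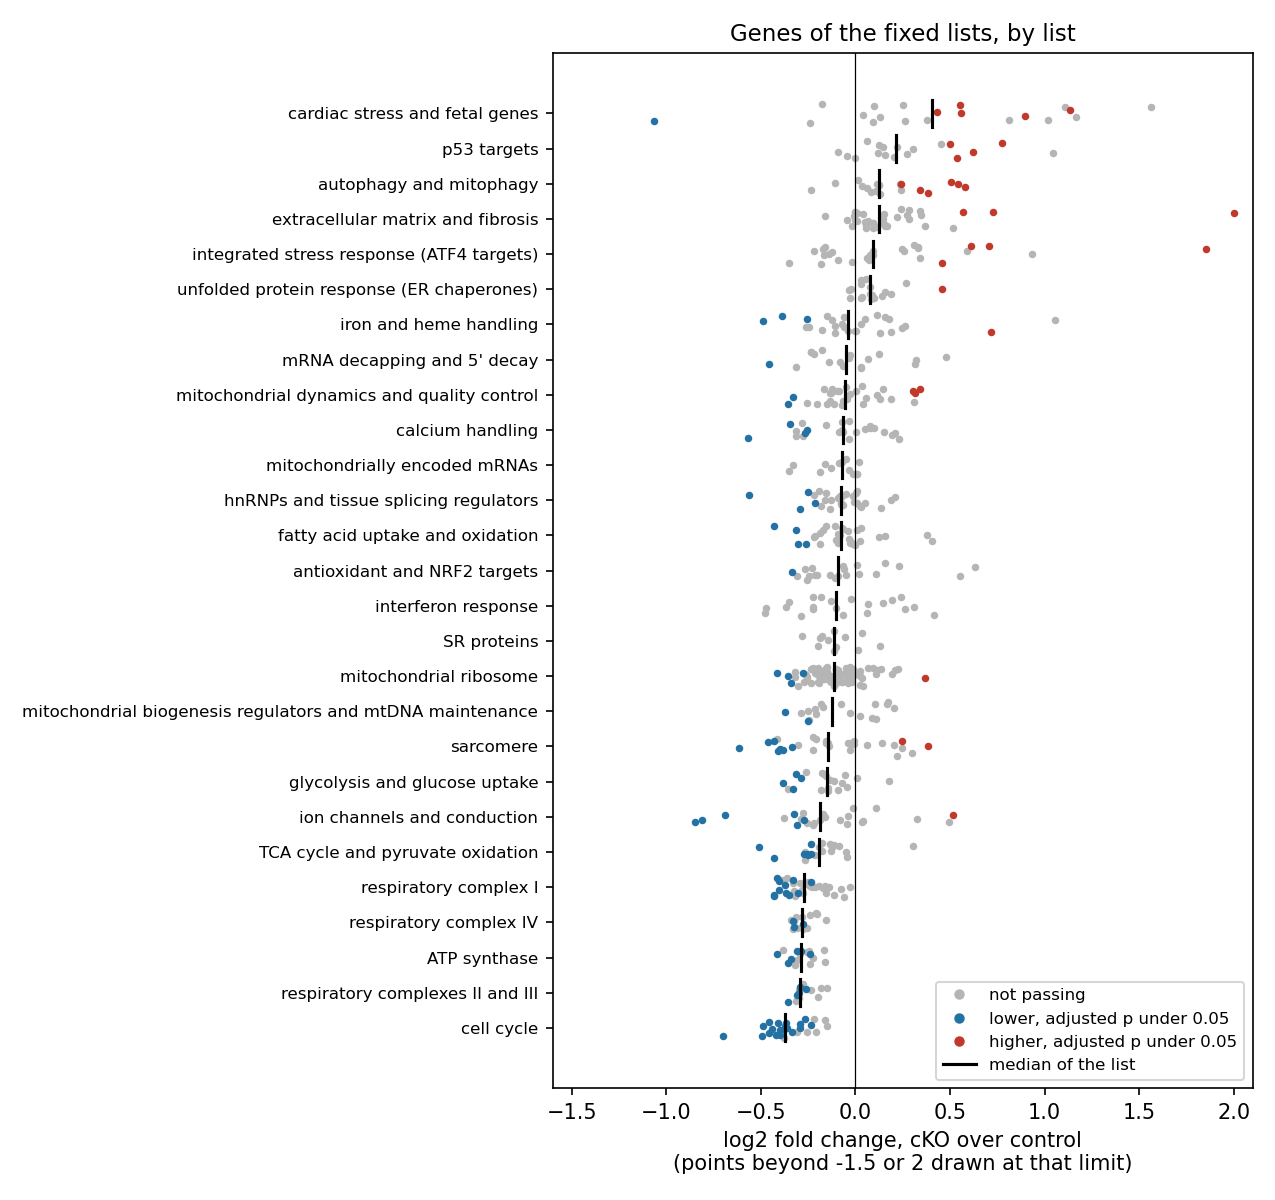
Log2 fold change, cKO over control, of the genes of 27 fixed lists from the authors' deposited table, 1 row per list, ordered by the list's median (black bar). Colored points passed an adjusted p under 0.05, and all points of the respiratory chain, ATP synthase and cell cycle rows lie left of 0.

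Cell cycle genes were lower, and had the smallest camera p of the fixed lists: 19 of 26 fell, 21 adjusted over the list alone, and all 26 values were negative with a median of -0.37 (camera adjusted p = 9.06e-20). Rrm2, a ribonucleotide reductase subunit, stood at -0.70 (SE 0.10, adjusted p = 1.52e-10), the cyclin Ccna2 at -0.49 and topoisomerase Top2a at -0.46 in the authors' deposited table. In the p53 list 4 of 18 genes rose (6 adjusted over the list alone; camera adjusted p = 1.23e-05), with the cell cycle inhibitor Cdkn1a at 0.62 (SE 0.10), Trp53inp1 at 0.78 and the nuclease Aen at 0.50 in the authors' deposited table. Myeloid and epicardial markers were higher in the same hearts, with medians of 0.57 and 0.60 and all values positive.

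Among contractile and electrical genes that passed, most were lower, while all 7 atrial markers had positive values in the same comparison, with a median of 0.50. Of 29 sarcomere genes, 7 fell and 2 rose (10 and 5 adjusted over the list alone), with the light chains Myl2 and Myl3 at -0.38 and -0.41, the myosin Myh7b at -0.62 (SE 0.13) and the actin-binding Nexn at -0.46 in the authors' deposited table. Their camera adjusted p was 0.00931, and 0.0702 with a preset correlation of 0.05. Of 25 ion channel and conduction genes, 6 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 1.23e-05). Kcnip2 and Kcnd2, which form the channel of the transient outward current, stood at -0.85 (SE 0.11) and -0.69, and Kcne1, partner of the channel of the slow delayed rectifier, at -0.81 (SE 0.10, adjusted p = 1.05e-13) in the authors' deposited table. Of 24 calcium handling genes, 4 fell (7 lower and 1 higher adjusted over the list alone), with the calcium release channel Itpr2 at -0.57 and phospholamban, Pln, at -0.27 in the authors' deposited table. This list had a camera adjusted p of 0.039, of 0.136 with a preset correlation of 0.05, of 0.137 by the rank-based test and of 0.058 among genes with a mean of at least 100.

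Cardiac stress genes rose in part, as did matrix and autophagy genes, beside the rise of myeloid markers: 5 of 20 rose and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.000282). The matricellular Ccn2 rose by 0.90 (SE 0.17), the matrix protein Cilp by 1.14, the LIM protein Fhl1 by 0.55 and the natriuretic peptide Nppb by 0.56 in the authors' deposited table. Nppa and Myh7 were at 0.81 and 0.38 with standard errors of 0.53 and 0.79 in the authors' deposited table and did not pass; these 2 were named after their values were seen. Of 38 genes of extracellular matrix and fibrosis, Spp1, tenascin Tnc (0.73) and thrombospondin Thbs1 (0.57) rose in the authors' deposited table, 3 in all and the same number adjusted over the list alone, while 31 of the 38 values were positive (camera adjusted p = 1.97e-05). Autophagy and mitophagy genes rose in 6 of 19 cases (8 adjusted over the list alone, camera adjusted p = 4.61e-07). Gabarapl1, a coat protein of autophagosomes, stood at 0.58 (SE 0.08), the cargo receptor Sqstm1 at 0.54 and Atg13 at 0.51 in the authors' deposited table. The others that rose were the lysosomal genes Lamp1 (0.34), Ctsd (0.38) and Ctsb (0.24) in the authors' deposited table. Ctsd and Ctsb were named after their values were seen. Of 27 targets of ATF4 in the integrated stress response, 4 rose, also adjusted over the list alone (camera adjusted p = 0.0927), namely Slc3a2 at 0.61, Asns at 0.71, Sesn2 at 0.46 and Chac1 at 1.86 in the authors' deposited table. In the unfolded protein response list the sensor Atf6, at 0.46 in the authors' deposited table, was the 1 of 18 genes that rose, also adjusted over the list alone (camera adjusted p = 0.0675, and 0.0285 by the rank-based test). In the interferon list 0 of 21 passed, also adjusted over the list alone, and 2 had an unadjusted p under 0.05 in the authors' Wald test (camera adjusted p = 0.315; 0 in the sleuth list); Stat2 stood at -0.23 in the authors' deposited table.

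Macrophage markers were higher in cKO hearts. Of 15 myeloid markers, 6 rose (11 adjusted over the list alone), all 15 values were positive, and their median was 0.57 (camera adjusted p = 1.62e-09). Lysozyme, Lyz2, rose by 1.11 (SE 0.17), the receptor Csf1r by 0.53 and Adgre1, the F4/80 antigen, by 0.75 in the authors' deposited table. Fibroblast, endothelial and mural markers moved less: 1 of 10 fibroblast markers fell (Thy1, -0.46), 1 of 14 endothelial markers rose (Vwf, 0.25) and 1 of 10 mural markers rose (Tagln, 0.47) in the authors' deposited table. Adjusted over the list alone these numbers were 1, 1 and 2, the last with 1 lower, and the camera adjusted p was 0.3, 0.536 and 0.95. Of 6 erythroid genes, the globin Hbb-bt fell by 0.71 in the authors' deposited table, 1 also adjusted over the list alone; the list's camera adjusted p was 0.0371, 0.0682 with a preset correlation of 0.05, and 0.0515 among genes with a mean of at least 100. Skeletal muscle markers had a positive median of 0.27, while the 1 of 9 that passed, also adjusted over the list alone, was negative: Tnni2 at -0.80 in the authors' deposited table (camera adjusted p = 0.716).

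Epicardial markers were higher in cKO as a list, and single markers of tissue at the edge of the heart did not pass. The 8 lymphoid, 7 adipocyte, 7 atrial, 5 nerve and 6 epicardial markers tested each gave 0 genes by the authors' Wald test, with 0, 0, 1, 1 and 4 at an unadjusted p under 0.05 and 0 in the sleuth list for each. Adjusted over the list alone, 2 epicardial markers were higher and the other counts stayed at 0. The brown fat gene Ucp1 and the lipid droplet gene Plin1 had log2 fold changes of 2.67 and 2.63 with standard errors of 2.22 and 1.57 in the authors' deposited table. The atrial light chains Myl7 and Myl4 stood at 0.41 and 0.50 with standard errors of 0.57 and 0.55 in the authors' deposited table. The epicardial genes Upk3b and Msln stood at 0.77 and 0.56, the Schwann cell gene Sox10 at 0.39, and the lymphocyte genes Ighm and Cd3d at 0.34 and 0.13 in the authors' deposited table. All 6 epicardial values were positive, with a median of 0.60 (camera adjusted p = 0.0109, and 0.0282 with a preset correlation of 0.05). Camera adjusted p was 0.0567 for the adipocyte and 0.0543 for the atrial list, each with 7 of 7 values positive and 0.00837 by the rank-based test, and 0.425 for the lymphoid and 0.16 for the nerve list.

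Genes of the splicing machinery moved little. None of 12 other SR protein genes passed in the authors' Wald test, also adjusted over the list alone, with 4 at an unadjusted p under 0.05 and 0 in the sleuth list. Srsf2 stood at -0.28 and Srsf5 at 0.01 in the authors' deposited table, and the list's camera adjusted p was 0.0183, or 0.0613 with a preset correlation of 0.05. Of 31 hnRNP and tissue splicing regulator genes, 4 fell, also adjusted over the list alone: Rbm24 at -0.29, Hnrnpa1 at -0.25, Rbfox1 at -0.56 and Rbpms at -0.22 in the authors' deposited table. That list's camera adjusted p was 0.0101, or 0.0768 with a preset correlation of 0.05. Of 18 genes of mRNA decapping and 5′ decay, Lsm2 fell by 0.46 in the authors' deposited table, with 2 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.458).

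Splicing differed in 610 events of 473 genes, and the commonest difference was a lower inclusion of exons in cKO. An event was counted where the authors' minimum change, exceeded with a probability of 0.95, was at least 10 points of PSI. Of 317 such exons, 234 had lower and 83 higher inclusion, 73.8% lower with an exact 95% interval of 68.6% to 78.6% (exact binomial p = 8.40e-18). Retained introns were also lower more often than higher, 93 against 42 (exact binomial p = 1.35e-05), but at a minimum change of 15 points this was 31 against 17 (exact binomial p = 0.0595). Alternative 3′ and 5′ splice sites split into 43 lower and 47 higher, and 30 lower and 38 higher, since the sites of a pair are read against each other. Exons passed more often than introns, with an odds ratio of 2.20 (95% interval 1.79 to 2.71; Fisher's exact p = 1.76e-15, adjusted over 6 class comparisons 1.06e-14). There is 1 value per group, so the spread between hearts is not shown here, and events of a gene are not independent. Counted at 1 per gene, 205 genes had lower and 77 higher exon inclusion.

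The transcription factor Sp4 had its exon on chromosome 12 (mm9 positions 119537111 to 119538631) at 89.6% in control and 21.6% in cKO in the authors' deposited table. Exon inclusion fell from 98.7% to 33.5% in the kinase gene Aak1, from 97.1% to 30% in Tmem116 and from 87.0% to 21% in the zinc finger gene Zfp865 in the authors' deposited table. Exons of Vamp1, a protein of vesicle fusion, and of Gm16008 fell to 33.1% and 21.8% from 95.7% and 83.7% in the authors' deposited table. In the opposite direction, an exon of the adaptor gene Synrg rose from 25.5% to 97.6%, one of the activin subunit Inhba from 21.9% to 82.7% and one of Elmo3 from 33.9% to 94.5% in the authors' deposited table. An intron of the cytokine receptor Il17ra (chromosome 6, mm9 positions 120428194 to 120428392) was retained at 2.97% in control and 94.8% in cKO in the authors' deposited table. An intron of Vill rose from 7.99% to 67.0%, while an intron of the kinase gene Braf fell from 81.7% to 21.7% and an intron of Lrg1 from 94.6% to 32.0% in the authors' deposited table. Among alternative splice sites, Znfx1, Strada, Cyp4f16, Amigo1 and Slc35c2 changed the most, with a site of Strada at 1.58% in control and 55.8% in cKO in the authors' deposited table.

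**Figure D3:**
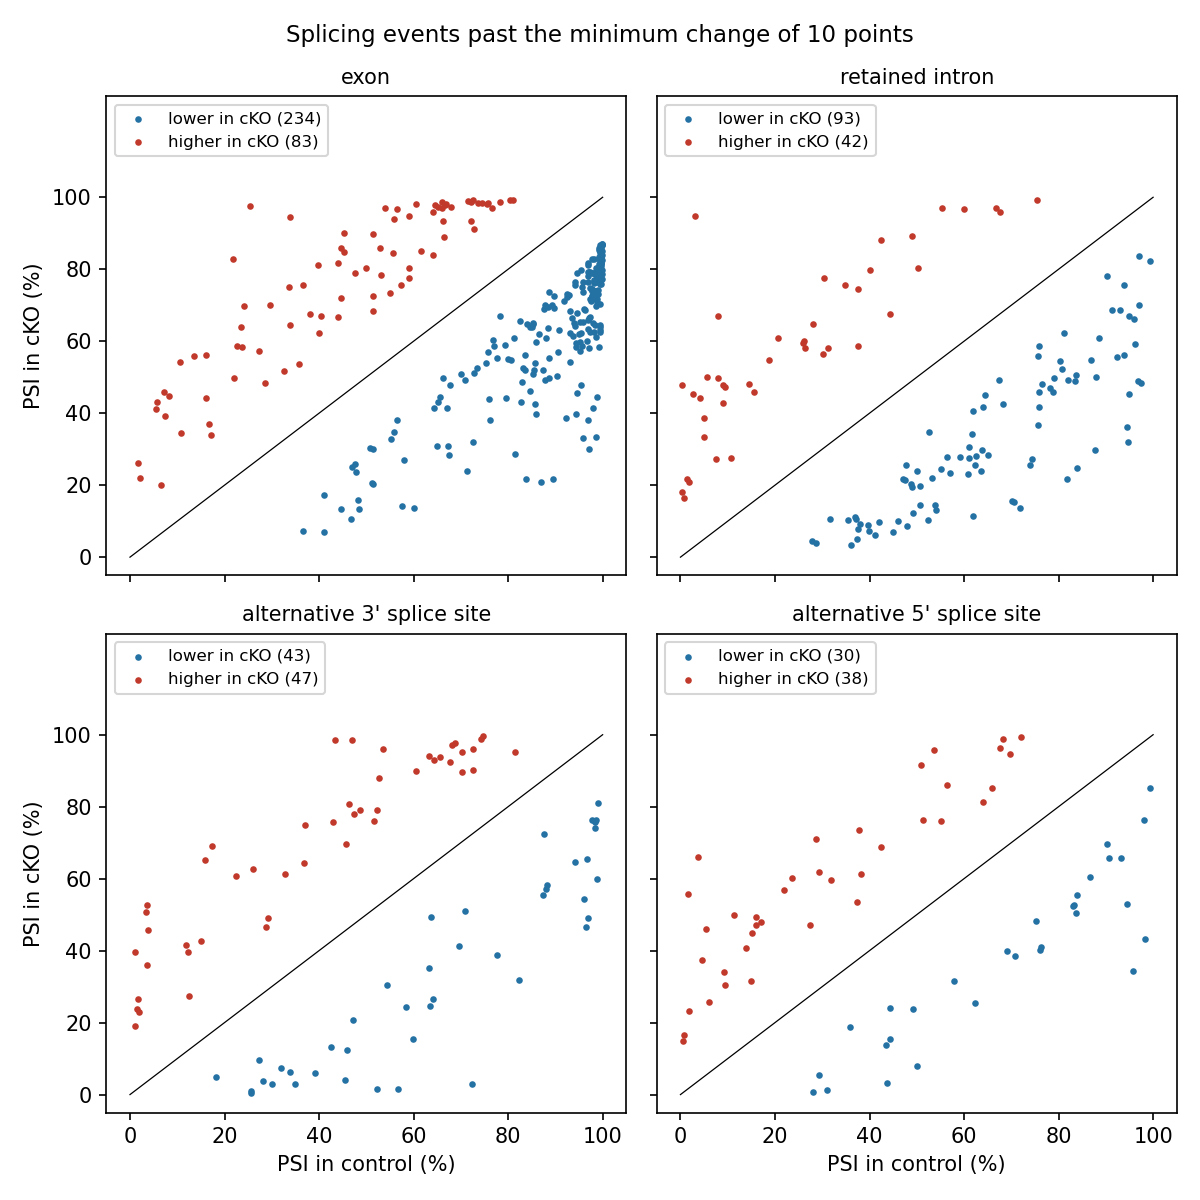
Inclusion level (PSI, %) in control (horizontal) and cKO (vertical) of the 610 events past the minimum change of 10 points, by class, with 1 value per group from the authors' deposited table. The diagonal marks equal inclusion, and 234 exons lie below it against 83 above.

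Genes with known alternative exons in heart held 13 events in 8 of 50 genes. In Tead1, a transcription factor of the Hippo pathway, an exon rose from 71.4% to 98.9% and the adjoining intron fell from 87.8% to 29.8% in the authors' deposited table. An exon of titin, Ttn, rose from 10.6% to 54.3% in the authors' deposited table. In the SR proteins, Srsf10 had a shift between alternative 3′ splice sites, from 87.4% to 55.4% for the more used of them in the authors' deposited table. The fixed mitochondrial lists held few events: 0 in the lists for complexes I to IV, the mitochondrial ribosome, fatty acids and the TCA cycle by vast-tools at this minimum change. The other mitochondrial lists held an alternative 5′ site of Atp5h, from 15% to 31.5%, an exon of the biogenesis regulator Gabpa, from 98.5% to 80.3%, and an alternative 3′ site of the fission factor Mief1 (Smcr7l in the file), from 3.69% to 52.7%, in the authors' deposited table. Oma1 had no event past the minimum change, and its largest difference was an exon at 96.7% in control and 91.4% in cKO in the authors' deposited table. Opa1, a substrate of OMA1, was chosen after its values were seen, and had an exon at 72.0% in control and 57.5% in cKO with a minimum change of 7 points in the authors' deposited table.

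Genes with a splicing difference also differed in total mRNA more often than other genes. Of 11550 genes with a value for both, 461 held an event and 962 differed in expression, with 73 in both against 38.4 by chance. The share of genes that differed in expression was 15.8% with an event and 8.02% without, an odds ratio of 2.16 (95% interval 1.64 to 2.81; Fisher's exact p = 6.30e-08, two-sided). The odds ratio was 1.78 (1.22 to 2.56) among genes above the median expression and 1.36 (1.10 to 1.66) with events at a minimum change of 5 points. Among them, the AMPK subunit Prkag3 had an exon at 98.8% in control and 44.6% in cKO and rose by 0.63 in the authors' deposited table. Tnc had an exon at 59.0% in control and 80.5% in cKO, and Atg13 one at 40.0% and 62.3% in the authors' deposited table. Prkag3, Tnc and Atg13 were taken from the 73 after their values were seen.

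The PSI of introns at the 5′ end of Myh7, the gene of the β myosin heavy chain, was higher in cKO. Only cKO hearts carry the Cre transgene with the Myh7 promoter, so whether these reads come from Myh7 or from the transgene stays open. Of the 27 listed Myh7 introns, the 3 ahead of exon 4, which holds the start codon, were at 45.5%, 21% and 47.8% in cKO in the authors' deposited table. The control values for these 3 introns were 2.61%, 1.76% and 0.414% in the authors' deposited table. The first lies on chromosome 14 at mm9 positions 55612463 to 55613347. None of the other 24 introns changed by more than 1.08 points.

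**Figure D4:**
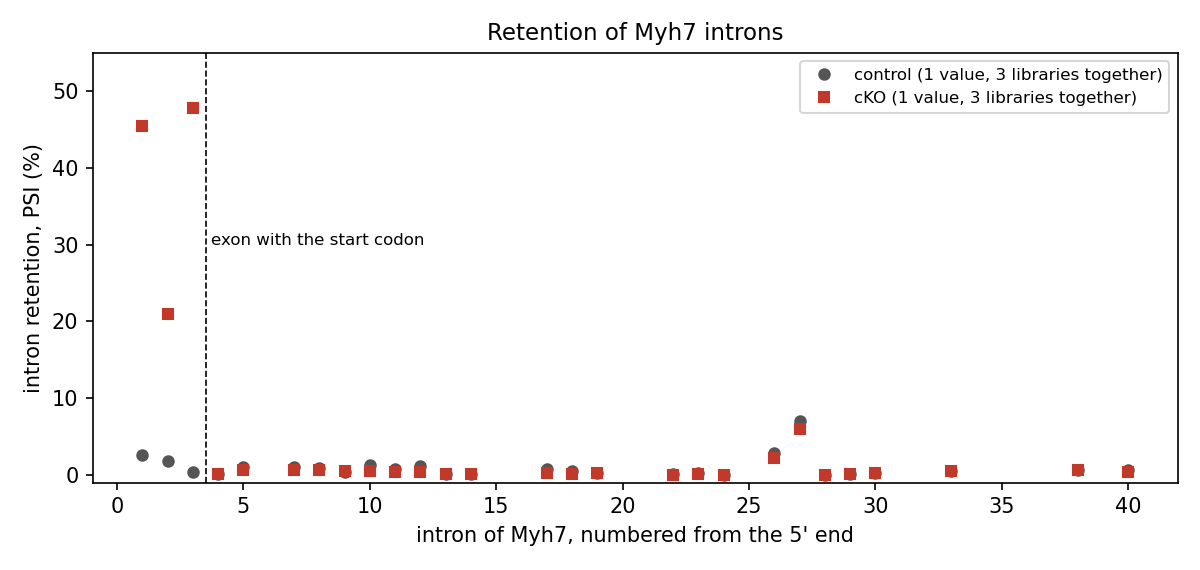
Intron retention (PSI, %) of the 27 listed Myh7 introns, numbered from the 5′ end (horizontal), with 1 value per group from the authors' deposited table. The 3 introns before the start codon exon (dashed line) reach 47.8% in cKO, and the others are alike in both groups. Whether RNA of the Cre transgene, carried only by cKO hearts, supplies these reads stays open.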

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

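The sleuth and featureCounts lists, the preset correlation of 0.05, the rank-based set test, the set test on abundant genes, single counting of identical genes and the minimum change of 5 points were chosen after seeing the result; the other alternatives were fixed before. Genes that passed numbered 1130; they were 529 at an adjusted p under 0.01, 303 with at least a 1.5-fold change, 517 in the sleuth list and 171 in the featureCounts list, and 921 with adjustment over every gene with a p-value, of which 901 were among the 1130. Srsf3, at 0.019, was not called by the authors' Wald test and is in the sleuth list; the cause was not tested. Splicing events numbered 610; they were 236 at a minimum change of 15 points, 5885 at any minimum change above 0, and 1677 at a minimum change of 5 points. The share of retained introns that were lower went from 68.9% to 64.6% at 15 points (31 against 17; exact binomial p = 0.0595, two-sided). None of the lists that passed changed direction in these set tests. The mural list, which passed in none, went from lower (adjusted p = 0.95) to higher (0.987) among abundant genes. Of 38 lists, 15 passed with a preset correlation of 0.05 and 24 by the rank-based test; among genes with a mean of at least 100, 19 passed, and 4 of the lists had too few members to test. Tests on counts, normalization, leaving out a library, fry, coverage minimums and other splits of the samples could not be run, since they need values per library. No paired analysis was possible because no values per library were used and the labels give no pairing of hearts. The first number of the sample titles is 3 for 2 control and 2 cKO hearts and differs for the others; the labels do not say whether it marks a litter or batch, and the comparison within it was not run.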

Other observations

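The test of room to rise and the test of promoter-proximal introns were written before their results; all other tests in this section, and the gene families and exon lengths below, were chosen after results were seen. Of 10 gene families tried, lysosomal genes were higher in cKO as a group, and histone genes were higher by camera with members in both directions. Of 39 lysosomal genes 8 rose (camera adjusted p = 1.28e-05), among them the protease Ctss at 0.68 and Gpnmb, a glycoprotein of macrophages, at 1.74 in the authors' deposited table. Lamp1, Ctsd and Ctsb are counted here and also among the autophagy genes that rose, so these results overlap. Myeloid markers were higher in the same hearts, with a median of 0.57 and 15 of 15 values positive. Of 18 V-ATPase subunits, which acidify lysosomes, 3 rose (camera adjusted p = 0.0211), with Atp6v0a1 at 0.48 in the authors' deposited table. Replication-dependent histone genes rose in 6 of 27 cases and fell in 2 (10 and 4 adjusted over the list alone, camera adjusted p = 0.00361), and 11 values were negative. The linker histone Hist1h1e stood at 1.90 with a mean of 54.8 normalized counts in the authors' deposited table. The more abundant Hist1h2ap, with a mean of 6876, stood at -0.58 in the authors' deposited table. Replication-dependent histone mRNAs mostly lack a poly(A) tail. Of 78 cytoplasmic ribosomal protein genes 76 had negative values and 1 fell (0 adjusted over the list alone), with a median of -0.14 (camera adjusted p = 4.84e-06). The other families had a camera adjusted p of 0.0461 (aminoacyl-tRNA synthetases, 2 of 19 higher), 0.174 (zinc finger genes), 0.324 (axoneme and cilium), 0.395 (cholesterol synthesis), 0.558 (mitochondrial carriers) and 0.929 (proteasome).

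Exons with lower inclusion in cKO were long more often than other exons. Of 234 such exons 48 (20.5%) exceeded 300 nt, against 2 of 83 (2.41%) with higher inclusion and 3628 of 100518 (3.61%) not called with a mean PSI of at least 10%, an odds ratio against the latter of 6.89 (95% interval 4.90 to 9.53; Fisher's exact p = 2.13e-22, two-sided). Median lengths were 184, 91 and 121 nt. The tRNA methyltransferase gene Trmt5 had such an exon at 92.2% in control and 38.7% in cKO, and Coasy, of coenzyme A synthesis, one at 88.6% and 49.8%, in the authors' deposited table. Total mRNA of genes with a lower exon rose in 35 and fell in 4 of 198 genes (exact binomial p = 3.35e-07, two-sided). This was not particular to lower exons: of 76 genes with a higher exon 13 rose and 1 fell (exact binomial p = 0.00183), and with any event 59 rose and 14 fell. Trmt5 stood at 0.97 and Coasy at 0.70 in the authors' deposited table.

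The 3 raised introns of Myh7 all precede its start codon exon. Their split from the other introns (Fisher's exact p = 0.000342, two-sided) was set after they were seen and restates the pattern, so whether RNA of the Cre transgene, which carries the Myh7 promoter, might supply these reads stays open. Of the 135 introns called across genes, 31.1% were higher, so introns past the minimum change did not mostly rise. A broad rise too small to pass it was not tested. In other genes the first 3 listed introns were raised more often than later ones, 13 of 21720 against 18 of 69297. The odds ratio was 2.30 (95% interval 1.04 to 4.98, Fisher's exact p = 0.032), which leaves a promoter-proximal effect open. Not every intron is listed, so these need not be the first 3 of each gene. No gene of 7240 had 2 or more of its first 3 listed introns raised, unlike Myh7. An effect of Srsf3 deletion on Myh7 splicing stays a hypothesis, which reads spanning the transgene junction would test.

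The 80 nuclear genes of the respiratory chain and ATP synthase had a median of -0.28, against -0.08 in lists matched for length, GC content and abundance. The lowest of 10000 matched lists was at -0.16, so none reached the median of the 80. How closely the matched genes resembled the 80 was not measured. They were also drawn independently, so the lists do not cover genes that vary together. The test therefore cannot exclude these features as the whole cause. Myeloid markers stood 0.62 above pooled fibroblast, endothelial and mural markers (permutation p = 1e-05, two-sided, the smallest these permutations can give), whose median was -0.05. A lower share of cardiomyocytes that raises all other cells alike would not give this. A lower share together with a rise of only some cell types was not tested. Epicardial (median 0.60, 6 of 6 positive), nerve (0.31, 5 of 5), lymphoid (0.27, 7 of 8) and adipocyte markers (2.67, 7 of 7) also had positive medians. Of these lists only the epicardial one passed by camera (adjusted p = 0.0109). The others had 0.16 (nerve), 0.425 (lymphoid) and 0.0567 (adipocyte, 0.00837 by the rank-based test). A higher share of these cells stays open. The median of the 80 genes differed by -0.17 from that of the mitochondrial ribosome list (permutation p = 1e-05, the same limit, though genes are not independent). The measured fall was thus not equal across mRNAs of mitochondrial proteins. The lists compared here were not matched for length, GC content or abundance. Srsf3 deletion lowering these mRNAs in cardiomyocytes remains a hypothesis, which single-nucleus RNA would test.

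Exons were lower more often than higher in cKO also at a mean PSI of 30% to 70%: 66 of 106, or 62.3% (95% interval 52.3% to 71.5%, exact binomial p = 0.0148, two-sided). The mean is over both groups, so this range holds exons near full inclusion in control, such as that of Aak1 (98.7% in control, 33.5% in cKO). The test therefore cannot decide whether lack of room is the whole cause. Part of the excess is tied to level, since 163 of 195 exons above 70% were lower, and under 50% only 24 of 50 were (48%, interval 33.7% to 62.6%). Fewer reads in cKO would raise low PSI values there; the bound first set against this, at least 50% lower under a mean PSI of 50%, was missed at 48%. A bound set afterwards was met, as the depth behind exons of near-full inclusion was higher in cKO by 0.39 on the log2 scale (bootstrap 95% interval 0.38 to 0.40). The same measure from introns gave 0.23. The depth behind the called exons themselves was not measured, so fewer reads are not excluded for them. That SRSF3 promotes inclusion of these exons may explain the direction, and stays a hypothesis that binding sites at the exons would test.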
